A study of Caenorhabditis elegans with 15 samples.

How the data were processed

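Expression was measured in whole wild-type N2 Caenorhabditis elegans with the Affymetrix C. elegans Genome Array, on total RNA from 15 samples with 1 array each. Per the labels, worms were kept at 20 °C with FUDR, which blocks the growth of progeny, from adult day 0. They were fed live OP50 bacteria until day 2 and UV-killed bacteria from then on. Ad libitum feeding (AL) used 1e10 bacteria per ml and calorie restriction (CR) 1e8 bacteria per ml. Intermittent fasting (IF) alternated fasting with ad libitum feeding every 2 days. AL had arrays of days 2, 4, 6, 8 and 10, CR of days 4, 6, 8 and 10, and IF of days 4, 6, 8, 10, 12 and 14. The labels used here do not state which period each IF sample ended, so IF arrays are named by day.

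The deposited values are log2 probe set intensities. Per the submitters' processing notes they were made with RMA in the affy package. RMA corrects for background, applies quantile normalization over arrays and summarises probes by median polish; the versions are not given in the sources used here. The base of the log was taken from RMA and from the range of the values. The median log2 value per array ran from 6.75 to 7.00. The number of arrays limits the precision.

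The table held 22625 probe sets, of which 77 were array controls. Among the others, 20766 were listed with 1 gene symbol, 887 with several symbols and 895 with none. The Entrez identifiers of 20701 of the single-gene probe sets matched a RefSeq gene table of assembly WBcel235, which was used for names only and updated 0 symbols. The 2981 genes with more than 1 probe set took the one with the highest mean over the 15 arrays, which left 17118 genes. No filter on level was applied. The probe sets with several genes or none were tested apart, and the AFFX control probe sets served only to compare 3' with 5' signal.

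Groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend=TRUE), two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of an adjusted p of 0.05. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. The diet comparisons used the 12 arrays of days 4, 6, 8 and 10, with the groups AL, CR, IF of days 4 and 8, and IF of days 6 and 10, and day as a factor, which left 5 residual degrees of freedom. The IF effect was the mean of both IF groups. The change with day was 1 linear slope shared by the diets beside the same groups, with 7 residual degrees of freedom, and slope differences used a slope per diet, with 5. A comparison inside IF set days 4, 8 and 12 against days 6, 10 and 14 on 6 arrays with a linear day term, with 3 residual degrees of freedom. Each diet and day had 1 array with no replicate, so every p-value measures only the spread between these arrays, part of which may be technical. Chance alone gives about 856 genes with an unadjusted p under 0.05 in each comparison. The counts inside IF and for the slope differences lay below that number.

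The choice of groups, tests, gene lists, named genes and most alternatives was made before the data were examined. Each comparison names up to 12 genes per direction with the largest change among genes past the threshold that moved the same way on every matched day, or with a slope of the same sign in all diets. Inside IF the 3 arrays of one period had to lie on one side of the 3 of the other after removal of the day trend. Genes without a symbol other than their sequence name were passed over. Each list adds up to 4 members with the smallest p, and where fewer than 5 genes passed, the 5 with the smallest p are given. Genes named outside this rule are said to be chosen after their values were seen. The vitellogenin, major sperm protein and histone genes have near-identical copies, so their probe sets may not tell family members apart.

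A set of 42 gene lists, written from gene nomenclature and textbook knowledge, held 3249 of the genes tested, 25 of them in more than 1 list. Lists were tested with camera at a preset correlation between genes of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The alternatives were camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way. List members were also counted when adjusted over the list alone.

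The procedure was tested on 5 simulated data sets of 17118 genes with 200 changed genes per comparison. Genes changed by 1 log2 unit were recovered in 91.2% of cases for CR against AL, 91.4% for IF against AL, 90.6% for IF against CR, 79.4% for IF days 4 and 8 against AL, and 81.4% for IF days 6 and 10 against AL. The recovery was 27.6% for the comparison inside IF, where genes changed by 2 log2 units were recovered in 73.8% of cases. For the difference in slope it was 2.0% in CR and 1.0% in IF at the smaller size simulated, and 28.8% and 23.4% at the larger. For the change per day it was 69.2% and 94.2%. For slopes and slope differences the simulated 1 and 2 log2 units were the whole change from day 4 to day 10, not a change per day. False calls made up at most 5.3% of those made in any comparison, and a planted list of 40 genes was called in 5 of 5 data sets in each. The simulated noise was drawn for each gene apart, around means that the fitted model can describe. Variation shared between genes and courses with day outside the model were left out. The rates of false calls and of list recovery hold only without these.

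The alternatives were a filter at the median level, the mean of a gene's probe sets, a further quantile normalization, limma's array weights, each array left out in turn, no day term, only the arrays of the groups compared, IF as 1 group, the IF periods on the 12 matched arrays and all 15 arrays for slopes. Chosen after seeing the data were the removal of the CR array of day 10 from comparisons without CR, and of each matched day from the change with day. The AL array of day 2 and the IF arrays of days 12 and 14 had no counterpart in the other diets and stayed out of the diet comparisons. Raw probe intensities were not analysed here.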

Results

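The data were 15 whole-worm expression profiles on arrays, 5 under ad libitum feeding (AL), 4 under calorie restriction (CR) and 6 under intermittent fasting (IF), taken every 2 days of adulthood. The series followed expression through ageing under these diets. Each profile held 22625 probe sets, and 17118 genes were compared. Correlation across genes between 2 arrays ran from 0.924, for AL day 10 and IF day 4, to 0.996, for IF days 12 and 14.

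Calorie restriction was set against ad libitum feeding on 4 matched days to find the genes that answered to dilute food. The invertebrate-type lysozyme gene ilys-3 was higher in CR by 2.72 on the log2 scale (SE 0.19, 4 arrays per diet, adjusted p = 2.04e-05). The lectin genes clec-9 (3.08, SE 0.36) and clec-60 (2.81, SE 0.16) rose with it. The fatty acid oxidation genes hacd-1, a hydroxyacyl-CoA dehydrogenase, and acs-2, an acyl-CoA synthetase known to rise on fasting, rose by 2.69 (SE 0.23) and 2.13 (SE 0.27). The arginine kinase gene argk-1 fell by 2.94 (SE 0.34) and cth-1, for a cystathionine gamma-lyase that makes cysteine, fell by 2.19 (SE 0.23).

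In CR 292 genes passed, 240 higher and 52 lower, while 2446 had an unadjusted p under 0.05. Among the further rises were clec-47 (2.43), far-7 (2.37), clec-61 (2.32), ilys-2 (2.29), dhs-26 (2.14), lys-6 (2.13) and pmp-5 (2.11). Among the further falls were lips-11 (-2.03), drd-50 (-1.94), clec-258 (-1.63), cpt-4 (-1.55), nspe-7 (-1.43), spp-18 (-1.27) and cyp-35B1 (-1.19). The count was 96 without the AL array of day 6, 127 without the AL array of day 8, 150 without the CR array of day 4 and 185 without the CR array of day 8, and 106 genes higher and 16 lower passed without the CR array of day 6. Without the AL array of day 10, 154 were higher and 65 lower. It was 679 with array weights, 460 with only the arrays compared, 38 with IF as 1 group and 3 with no day term. In both of the last settings ilys-3, clec-9, hacd-1, acs-2, argk-1 and cth-1 no longer passed, though their log2 differences stayed the same. Without the CR array of day 6 clec-258 (-1.36), cpt-4 (-1.45) and spp-18 (-1.26) did not pass, nor did they, cpt-4 apart, without the AL array of day 6 (-1.69 and -1.09) or of day 8 (-1.47 and -1.19); nspe-7 did not without the AL array of day 6 (-1.32) or 8 (-1.26), nor spp-18 without the CR array of day 8 (-1.19).

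In CR, of 56 neuropeptide genes, 6 rose, 0 fell and 50 did not pass, among them nlp-18 (0.82, SE 0.14) as a rise that no longer passed without the AL (0.71) or CR (0.77) array of day 6. Adjusted over the list alone, 39 rose. The list's median was 0.37 (camera adjusted p = 3.12e-21, adjusted p = 0.399 with an estimated correlation). Of 70 lysozyme, saposin and antimicrobial peptide genes, 9 rose, 1 fell and 60 did not pass, with a median of 0.17, lys-10 at 1.84 and lys-4 at 1.49. There were 18 up and 2 down when adjusted over the list alone (camera adjusted p = 4.12e-07, adjusted p = 0.399 with an estimated correlation). Of 39 cathepsins and other digestive proteases, 5 rose, 1 fell and 33 did not pass, with cpr-2 at 1.82. There were 13 up and 1 down when adjusted over the list alone (camera adjusted p = 0.000239, adjusted p = 0.207 with an estimated correlation). Of 64 UDP-glycosyltransferases, 7 rose, 1 fell and 56 did not pass, with ugt-66 at 1.68. There were 16 up and 1 down when adjusted over the list alone (camera adjusted p = 1.28e-05, adjusted p = 0.399 with an estimated correlation). Beside these, in CR the neuron markers had a median of 0.12 (3 up when adjusted over the list alone, camera adjusted p = 0.000285, adjusted p = 0.399 with an estimated correlation) and the pharynx markers 0.25 (0 up when adjusted over the list alone, camera adjusted p = 0.000744, adjusted p = 0.399 with an estimated correlation). The medians were 0.13 for intestine markers (5 up when adjusted over the list alone, camera adjusted p = 0.0677, adjusted p = 0.399 with an estimated correlation), 0.02 for hypodermis markers (0 when adjusted over the list alone, camera adjusted p = 0.641, adjusted p = 0.883 with an estimated correlation) and -0.15 for germ granule and germline stem cell genes (0 when adjusted over the list alone, camera adjusted p = 0.00186, adjusted p = 0.474 with an estimated correlation). Body wall muscle markers had a median of 0.17 (1 up when adjusted over the list alone, camera adjusted p = 0.0053, adjusted p = 0.558 with an estimated correlation). Without the CR array of day 10 the intestine median was 0.02 and that of body wall muscle markers 0.07 (camera adjusted p = 0.173).

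Of 74 sperm genes in CR, 1 fell, ssq-3 (-0.78, SE 0.17), and 73 did not pass (0 when adjusted over the list alone), with a list median of -0.38 (camera adjusted p = 1.08e-15, adjusted p = 0.399 with an estimated correlation). Of 30 oocyte, eggshell and early embryo genes, 1 fell, puf-3 (-0.43, SE 0.09), and 29 did not pass (2 down when adjusted over the list alone), with a median of -0.19 (camera adjusted p = 6.74e-08, adjusted p = 0.406 with an estimated correlation). The fatty acid oxidation list went both ways, with 3 up, 1 down and 36 not passed of 40. There were 7 up and 6 down when adjusted over the list alone (camera adjusted p = 0.864, adjusted p = 0.918 with an estimated correlation). Camera called 18 of the 42 lists in CR, 11 higher and 7 lower, and 0 with an estimated correlation. The CR array of day 10 stood apart in its control RNAs, whose 3' signal exceeded the 5' signal by 2.81 log2 units for dap and 2.77 for thr, against at most 1.78 and 1.79 on the other arrays. Without it 231 genes passed, 191 of them among the 292, puf-3 (-0.39) and ssq-3 (-0.65) did not, camera called 13 of the 18 lists, and the medians were 0.11 for lysozymes and -0.10 for oocyte genes. The call of ssq-3 was lost without any 1 of the 8 arrays compared (-0.65 to -0.90), and that of puf-3 without either array of day 6 (-0.37 in AL, -0.38 in CR), 8 (-0.41, -0.44) or 10 (-0.41, -0.39).

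**Figure D1:**
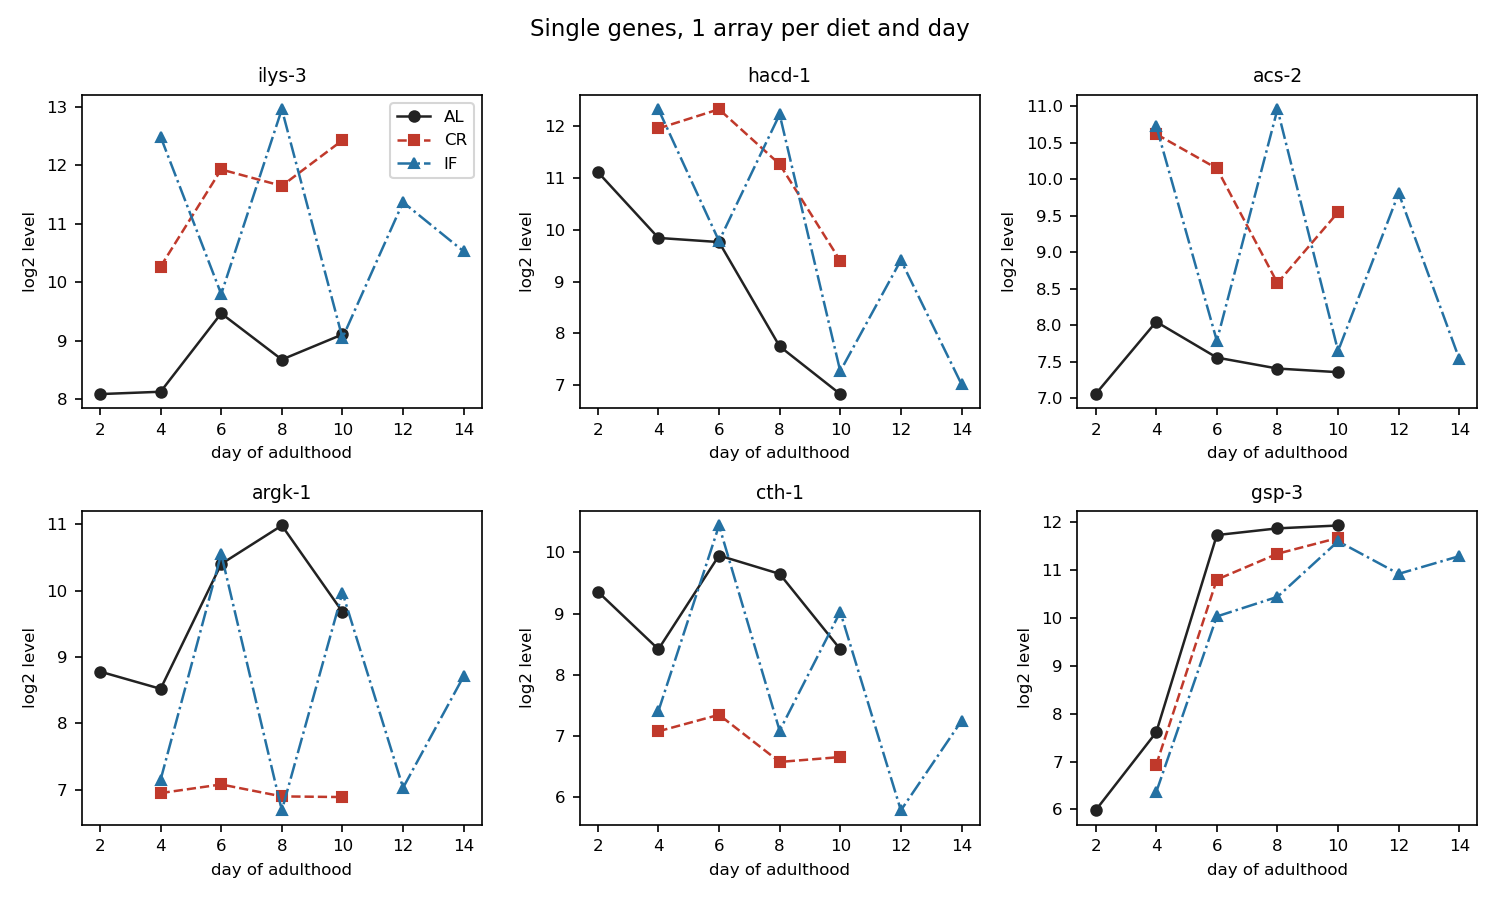
Log2 level (vertical axis) of ilys-3, hacd-1, acs-2, argk-1, cth-1 and gsp-3 on each array against day of adulthood (horizontal axis), with 1 point per array for AL (black circles), CR (red squares) and IF (blue triangles). The IF points of acs-2 alternate from 10.73 on day 4 to 7.79 on day 6 and 10.96 on day 8, while the AL points of days 4 to 10 lie between 7.36 and 8.05.

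Intermittent fasting was set against ad libitum feeding on the same 4 days. In IF the cathepsin B-like protease gene cpr-2 was higher by 2.15 on the log2 scale (SE 0.14, 4 arrays per diet, adjusted p = 2.74e-05). The lectin genes clec-61 (2.18, SE 0.17) and clec-60 (1.75, SE 0.16) rose, as did hacd-1 (1.85, SE 0.23) and acs-2 (1.69, SE 0.27). The insulin-like peptide gene ins-7 fell by 1.31 (SE 0.32, adjusted p = 0.028), and lips-11, related to lipases, fell by 2.50 (SE 0.19). The sperm phosphatase gene gsp-3 fell by 1.18 (SE 0.17). The fall of ins-7 no longer passed without the array of day 6 or 8 in AL, or of day 8 or 10 in IF (ins-7 adjusted p from 0.131 to 0.17), and hacd-1 and acs-2 did not pass with IF as 1 group (adjusted p = 0.0986 and 0.145).

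In IF 1151 genes passed, 514 higher and 637 lower, and 1021 of them had the same sign on all 4 days; 3284 had an unadjusted p under 0.05. Further rises included dhs-26 (1.67), aqp-1 (1.57), clec-52 (1.45), asah-1 (1.36), dod-3 (1.34) and pcp-1 (1.31). Further falls were clec-174 (-2.27), col-183 (-1.45), ssp-16 (-1.27) and gipc-2 (-1.22). The count was 336 without the IF array of day 6, 350 without the AL array of day 6, 432 without the IF array of day 8 and 438 without the AL array of day 8. Without the IF array of day 6 the balance turned to 177 higher and 159 lower, and without the AL array of day 10 it was 268 higher and 529 lower. With IF as 1 group it was 687, of which 27.9% were higher against 44.7% before, and with no day term it was 1. Without the IF array of day 6 clec-52 (1.36) and gipc-2 (-0.96) no longer passed, without the IF array of day 8 gipc-2 (-1.09), asah-1 (1.2) and dod-3 (0.95), without the AL array of day 6 gipc-2 (-1.01) and dod-3 (1.35), without the AL array of day 8 asah-1 (1.16) and dod-3 (0.99), and without the IF array of day 10 dod-3 (1.12).

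In IF, of 74 sperm genes, 0 rose, 45 fell and 29 did not pass (64 fell when adjusted over the list alone), among them gsp-4 (-1.09, SE 0.14) and ssq-3 (-1.19), with a median of -0.80 (camera adjusted p = 3.55e-40, adjusted p = 0.194 with an estimated correlation). Alongside, 16 of 56 neuropeptide genes rose, 0 fell and 40 did not pass, with nlp-18 at 0.69, which no longer passed without the AL array of day 6 (0.58) or the IF array of day 6 (0.61) or 8 (0.64). There were 34 up when adjusted over the list alone (camera adjusted p = 2.94e-16, adjusted p = 0.267 with an estimated correlation). Of 12 small heat shock proteins, 4 rose, 0 fell and 8 did not pass, with hsp-16.20 at 1.00 (SE 0.12) and hsp-12.6 at 0.80. There were 10 up when adjusted over the list alone (camera adjusted p = 2.31e-07, adjusted p = 0.145 with an estimated correlation). Beside these, in IF the neuron markers had a median of 0.19 (6 up when adjusted over the list alone, camera adjusted p = 0.000158, adjusted p = 0.22 with an estimated correlation) and the pharynx markers 0.25 (0 up when adjusted over the list alone, camera adjusted p = 0.00505, adjusted p = 0.352 with an estimated correlation). The medians were 0.16 for intestine markers (2 up when adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.22 with an estimated correlation), 0.04 for hypodermis markers (0 when adjusted over the list alone, camera adjusted p = 0.805, adjusted p = 0.916 with an estimated correlation) and -0.21 for germ granule and germline stem cell genes (0 when adjusted over the list alone, camera adjusted p = 0.000625, adjusted p = 0.352 with an estimated correlation). Body wall muscle markers had a median of 0.21 (0 when adjusted over the list alone, camera adjusted p = 0.000186, adjusted p = 0.43 with an estimated correlation). Their mean level in IF lay below AL on day 4 (10.40 against 10.62) and above it on days 6, 8 and 10.

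In IF, of 64 UDP-glycosyltransferases, 14 rose, 1 fell and 49 did not pass, with ugt-66 at 1.32 and ugt-51 at 0.97. There were 21 up and 1 down when adjusted over the list alone (camera adjusted p = 2.25e-08, adjusted p = 0.194 with an estimated correlation). Of 45 glutathione S-transferases, 6 rose, 0 fell and 39 did not pass, with gst-4 at 0.73. There were 8 up when adjusted over the list alone (camera adjusted p = 0.00244, adjusted p = 0.352 with an estimated correlation). Of 73 cytochromes P450, 8 rose, 0 fell and 65 did not pass. There were 11 up when adjusted over the list alone (camera adjusted p = 0.00137, adjusted p = 0.22 with an estimated correlation). Of 13 genes known to be raised by the transcription factor DAF-16 (class I), 4 rose, 0 fell and 9 did not pass, with hil-1 at 1.05 and dod-6 at 1.07. There were 7 up when adjusted over the list alone (camera adjusted p = 7.42e-05, adjusted p = 0.194 with an estimated correlation). The calls of gst-4 (0.66 and 0.58) and hil-1 (0.97 and 0.93) were lost without the AL array of day 6 and without the IF array of day 8, and that of gst-4 (0.61) without the IF array of day 6. Camera called 24 of the 42 lists in IF, 19 higher and 5 lower, and 0 with an estimated correlation.

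The IF arrays of days 4 and 8 were set against AL, and those of days 6 and 10 likewise, to follow the alternation of fasting and feeding. The fit took its day effects from AL and CR together, so CR arrays and AL arrays of the other days also enter each value. On days 4 and 8 ilys-3 was higher than in AL by 4.40 on the log2 scale (SE 0.25, 2 IF arrays in a fit of 12 arrays, adjusted p = 3.94e-06 by limma), or 21.2-fold. The fat metabolism genes hacd-1 (3.41, SE 0.31) and acs-2 (3.25, SE 0.35) and the alcohol dehydrogenase gene adh-1 (3.25, SE 0.27) rose, while argk-1 fell by 2.89 (SE 0.45) and cth-1 fell by 1.78 (SE 0.31). On days 6 and 10 ilys-3 lay at 0.05 relative to AL, hacd-1 at 0.30, acs-2 at 0.13 and argk-1 at 0.28, and none of these passed. The difference between the pairs of days, tested on the 12 matched arrays, passed for ilys-3 (4.35, SE 0.33), hacd-1 (3.12, SE 0.40), acs-2 (3.12, SE 0.46), argk-1 (-3.17, SE 0.59) and cth-1 (-2.32, SE 0.41), which were singled out after their values were seen.

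On days 4 and 8, 1157 genes passed, 718 higher and 439 lower, with 3365 at an unadjusted p under 0.05. The rises included far-7 (3.65), clec-9 (3.37), clec-61 (3.31), cpr-2 (3.14), clec-60 (2.92), aqp-1 (2.81), ilys-2 (2.74) and the neuropeptide gene nlp-51 (2.17). The falls included drd-50 (-2.99), clec-174 (-2.65), sysm-1 (-2.42), folt-2 (-1.95), irg-8 (-1.84) and dod-19 (-1.82). On days 6 and 10 3 genes passed, C30G12.2 (2.67, SE 0.30) and drd-5 (1.02, SE 0.14) higher and lips-11 (-2.58, SE 0.25) lower, with 1769 at an unadjusted p under 0.05. Without the IF array of day 4 the balance on days 4 and 8 turned to 636 higher and 790 lower. For days 4 and 8 the count was 302 without the IF array of day 8, when argk-1 (-2.05, adjusted p = 0.081) and cth-1 (-1.44, adjusted p = 0.127) no longer passed, nor sysm-1 (-2.77; -2.07 without the IF array of day 4), 500 without the AL array of day 8, 303 with only the arrays compared and 34 with no day term. For days 6 and 10 it was 91 without the AL array of day 10, 14 without the AL array of day 4, 1 without the AL or the IF array of day 6 and 0 without the IF array of day 10. It was 13 with array weights, 50 with only the arrays compared and 0 with no day term.

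On IF days 4 and 8, of 12 small heat shock proteins, 7 rose, 0 fell and 5 did not pass, among them hsp-16.20 (1.87, SE 0.16), hsp-12.3 (1.94) and hsp-12.6 (1.74), with 7 up when adjusted over the list alone (camera adjusted p = 2.04e-08, adjusted p = 0.19 with an estimated correlation). Of the 13 DAF-16 class I genes, 7 rose, 0 fell and 6 did not pass, with hil-1 at 1.89. There were 7 up when adjusted over the list alone (camera adjusted p = 7.25e-08, adjusted p = 0.197 with an estimated correlation). Of 7 genes lowered by DAF-16 (class II), 3 fell, 0 rose and 4 did not pass, with dod-24 at -1.47 and dod-17 at -0.98. There were 4 down when adjusted over the list alone (camera adjusted p = 0.00726, adjusted p = 0.197 with an estimated correlation). Of 35 genes of fatty acid desaturation, elongation and synthesis, 9 rose, 3 fell and 23 did not pass, with the desaturase genes fat-5 (1.51, SE 0.14) and fat-6 (0.83) and the elongase genes elo-6 (1.68) and elo-2 (0.69) as rises. There were 11 up and 6 down when adjusted over the list alone (camera adjusted p = 0.0484, adjusted p = 0.197 with an estimated correlation). Of 15 genes of gluconeogenesis, the glyoxylate cycle and trehalose, 3 rose, 1 fell and 11 did not pass, with the trehalose synthase genes tps-1 (0.87) and tps-2 (0.84) and the isocitrate lyase gene icl-1 (0.69) as rises and pck-3 (-0.93) as the fall. There were 6 up and 1 down when adjusted over the list alone (camera adjusted p = 0.0031, adjusted p = 0.197 with an estimated correlation). Without the IF array of day 8, elo-6 (0.93), elo-2 (0.59), fat-6 (0.42), tps-1 (0.76), tps-2 (0.58) and pck-3 (-0.41) no longer passed, and icl-1 (0.34), dod-24 (-1.27) and dod-17 (-0.42) did not without the IF array of day 4. Without the AL array of day 8 fat-6 (0.72), tps-2 (0.79), pck-3 (-0.81), dod-24 (-1.36) and dod-17 (-1.13) did not pass, without that of day 6 pck-3 (-0.88), icl-1 (0.68) and dod-17 (-0.95), without that of day 4 icl-1 (0.50) and dod-17 (-0.89), and without that of day 10 icl-1 (0.67). The list fatty acid desaturation, elongation and synthesis was not called with array weights (camera adjusted p = 0.0566) or a further quantile normalization (0.0759).

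On the same days, of 56 neuropeptide genes, 24 rose, 0 fell and 32 did not pass, with nlp-39 at 1.26 (SE 0.19) and flp-9 at 1.03, neither of which passed without the IF array of day 8 (1.03 and 1.01). There were 40 up when adjusted over the list alone (camera adjusted p = 3.43e-22, adjusted p = 0.197 with an estimated correlation). Of 74 sperm genes, 40 fell, 0 rose and 34 did not pass (56 down when adjusted over the list alone), with a median of -0.93 (camera adjusted p = 2.33e-31, adjusted p = 0.197 with an estimated correlation). Beside these, on days 4 and 8 the neuron markers had a median of 0.21 (7 up when adjusted over the list alone, camera adjusted p = 0.000362, adjusted p = 0.197 with an estimated correlation) and the pharynx markers 0.37 (3 up when adjusted over the list alone, camera adjusted p = 0.00319, adjusted p = 0.273 with an estimated correlation). The medians were 0.24 for intestine markers (1 up when adjusted over the list alone, camera adjusted p = 0.0422, adjusted p = 0.208 with an estimated correlation), -0.03 for hypodermis markers (0 when adjusted over the list alone, camera adjusted p = 0.276, adjusted p = 0.552 with an estimated correlation) and -0.19 for germ granule and germline stem cell genes (0 when adjusted over the list alone, camera adjusted p = 0.0187, adjusted p = 0.537 with an estimated correlation). That of body wall muscle markers was 0.10 (0 when adjusted over the list alone, camera adjusted p = 0.172, adjusted p = 0.711 with an estimated correlation). The call of the intestine markers was lost with array weights (camera adjusted p = 0.0742), a further quantile normalization (0.0638) and without the CR array of day 10 (0.051). On days 6 and 10 the sperm list had a median of -0.61 (51 down when adjusted over the list alone, camera adjusted p = 6.36e-34, adjusted p = 0.34 with an estimated correlation) and the UDP-glycosyltransferase list 0.23. Of the latter, 8 were up when adjusted over the list alone (camera adjusted p = 6.68e-09, adjusted p = 0.34 with an estimated correlation). Camera called 27 of the 42 lists on days 4 and 8 and 14 on days 6 and 10, and 0 with an estimated correlation.

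Inside IF, days 4, 8 and 12 were set against days 6, 10 and 14 on the IF arrays alone. Of all genes 0 passed by limma, with 562 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0982, shared by sysm-1 (-3.98, SE 0.46), acs-2 (2.70, SE 0.31), clec-67 (-2.01, SE 0.24), argk-1 (-3.03, SE 0.38) and F28H7.3 (-2.04, SE 0.25). On the 12 matched arrays, with day effects from AL and CR together, IF days 4 and 8 were set against IF days 6 and 10. That contrast called 157 genes, 110 higher and 47 lower on days 4 and 8. Among them were far-7 (3.84, SE 0.32), adh-1 (3.31, SE 0.36), hsp-12.6 (1.89, SE 0.23), fat-5 (1.18, SE 0.19), sysm-1 (-4.22, SE 0.60) and folt-2 (-2.82, SE 0.30). Array weights gave 45 genes on the 6 arrays, and leaving out an array gave 67 without day 8, 30 without day 4, 22 without day 12 and 9 without day 14. Camera called 21 of the 42 lists and 0 with an estimated correlation. Array weights kept 17 of them and turned those of lysozymes and of neuropeptides, and a further quantile normalization kept 11. Of the lists, sperm had a median of -0.77 (0 when adjusted over the list alone, camera adjusted p = 1.64e-10, adjusted p = 0.907 with an estimated correlation) and the DAF-16 class I genes 0.27. Of the latter, 2 were up when adjusted over the list alone (camera adjusted p = 1.09e-05, adjusted p = 0.907 with an estimated correlation). The sperm value cannot be read as a difference between periods alone, since the fit had only a linear day term. The sperm mean stepped up from day 4 to day 6 in AL (7.86 to 10.13) and CR (7.38 to 9.61) too. On the 12 matched arrays gsp-4 lay at -0.35 against -0.96 on the 6 IF arrays, and msd-2 at -0.59 against -1.19.

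Intermittent fasting was set against calorie restriction to ask whether the 2 restricted diets differed. Of all genes 0 passed by limma, with 1242 at an unadjusted p under 0.05, a smallest adjusted p of 0.0542 and 4 arrays per diet. The smallest p-values, which did not pass, belonged to hpd-1 (0.93, SE 0.12), pho-11 (1.01, SE 0.14), C01G10.1 (-0.51), F40G12.5 (1.01) and clec-60 (-1.06, SE 0.16). The contrast averaged IF days 4 and 8 with IF days 6 and 10, so opposite differences could cancel. By day, IF minus CR ran from -2.68 to 0.38 for clec-60 and from -0.66 to 2.78 for F40G12.5. It kept its sign on every matched day for hpd-1, pho-11 and C01G10.1. The IF pairs of days were not set against CR apart, so the 0 does not show that the diets were alike. With array weights 17 genes passed, with only the arrays compared 29, and without a single array 9 (CR day 10), 7 (IF day 4), 5 (IF day 8) and 3 (IF day 10). The sperm list lay lower in IF than in CR by a median of -0.40 (30 down when adjusted over the list alone, camera adjusted p = 5.53e-31, adjusted p = 0.277 with an estimated correlation), and the glutathione S-transferase list higher by 0.16. Of the latter, 5 were up when adjusted over the list alone (camera adjusted p = 4.38e-07, adjusted p = 0.277 with an estimated correlation). Camera called 17 of the 42 lists and 0 with an estimated correlation. Without the CR array of day 10, 9 of the 17 calls held and the histone list turned.

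The CR and IF effects were set side by side across genes. Of the 292 genes called in CR, 290 had the same sign in IF, and 221 were called in both, 190 higher and 31 lower, against 7.21 and 1.94 for independent lists. Among the shared calls were clec-60, hacd-1, acs-2 and lips-11. The IF effect here is the mean of both pairs of days. On IF days 6 and 10 clec-60 (0.57), hacd-1 (0.30) and acs-2 (0.13) did not pass, while lips-11 (-2.58) did. Of the 292 genes, 247 were also called with the same sign on IF days 4 and 8, whereas only 3 genes passed at all on IF days 6 and 10. The CR and IF comparisons use the same AL arrays, which alone gives a positive relation, so unchanged groups were simulated in 100 data sets. The covariance across genes was 0.0502 against a simulated mean of 0.00919 and a highest simulated value of 0.00979, a difference of 0.041. With 2 AL arrays given to each diet, in all 6 ways, the correlation across genes ran from 0.346 to 0.66. With shared arrays it was 0.794, against a simulated mean of 0.5 and a highest simulated value of 0.524; the split arrays were not simulated. The simulated noise was drawn for each gene apart, so the simulated ranges leave out variation shared between genes and are too narrow where genes vary together. Genes are not independent replicates.

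The change with day was followed on days 4 to 10 with 1 slope for the 3 diets, to describe adult ageing. The slope rests on 4 days, while the fit counted the 3 arrays of a day as independent. Where the arrays of a day depart from the line together, the SEs and p-values are too small and the calls too many. Sperm genes rose, among them gsp-3 at 0.70 log2 units per day (SE 0.13, 12 arrays, adjusted p = 0.00144), sss-1 at 0.77 (SE 0.09) and spe-27 at 0.43. Of 5 vitellogenins, which encode yolk proteins, 5 fell, also when adjusted over the list alone (camera adjusted p = 0.00627, adjusted p = 0.301 with an estimated correlation), with a median slope of -0.105 per day in AL, -0.095 in CR and -0.035 in IF. The DAF-16 class II gene dod-24 fell by 0.71 per day (SE 0.06) and the lysozyme gene ilys-5 fell by 0.75 (SE 0.07). The muscle myosin gene unc-54 fell by 0.28.

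With day 5981 genes passed, 2598 rising and 3383 falling, and 5956 had the same sign in all diets. Other rises were gipc-2 (0.74), spsp-1 (0.71), msd-4 (0.71) and cyc-2.2 (0.68), and other falls clec-174 (-0.75), pud-4 (-0.67), asp-14 (-0.65) and clec-66 (-0.58). Without the arrays of day 10 the count was 2691 and the balance turned to 1424 rising and 1267 falling, and with dim genes left out it was 3948 of 8559 tested.

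Sperm, meiotic and germ granule lists rose with day. Of 74 sperm genes, 66 rose, 0 fell and 8 did not pass (67 up when adjusted over the list alone), with a median of 0.52 per day (camera adjusted p = 2.04e-26, adjusted p = 0.301 with an estimated correlation), or 0.20 without day 4. The AL mean of the sperm list was 7.86 on day 4, 10.13 on day 6, 10.31 on day 8 and 10.52 on day 10. Of 21 meiotic chromosome genes, 17 rose, 0 fell and 4 did not pass, with syp-1 of the synaptonemal complex at 0.25. There were 19 up when adjusted over the list alone (camera adjusted p = 5.98e-09, adjusted p = 0.346 with an estimated correlation). Of 20 germ granule and germline stem cell genes, 15 rose, 0 fell and 5 did not pass, with the helicase gene glh-1 at 0.20. There were 17 up when adjusted over the list alone (camera adjusted p = 3.44e-08, adjusted p = 0.301 with an estimated correlation). The meiotic and germ granule medians of 0.17 and 0.14 per day were 0.27 and 0.23 without day 4, and 0.12 and 0.09 without day 10. The oocyte list was not called, with 1 up, 2 down and 27 not passed of 30 (1 up and 2 down when adjusted over the list alone, camera adjusted p = 0.704, adjusted p = 0.946 with an estimated correlation), though its median turned from -0.03 to 0.15 without day 4 (camera adjusted p = 8.41e-07) and was -0.08 without day 6 (camera adjusted p = 0.00166) and -0.16 without day 10 (camera adjusted p = 4.95e-07). With a day left out, camera was run at the preset correlation only.

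With day, of 56 neuropeptide genes, 46 fell, 0 rose and 10 did not pass, with flp-2 at -0.20 per day. There were 52 down when adjusted over the list alone (camera adjusted p = 3.47e-13, adjusted p = 0.346 with an estimated correlation). Of 146 cuticle collagens, 89 fell, 2 rose and 55 did not pass, with col-160 at -0.42. There were 100 down and 2 up when adjusted over the list alone (camera adjusted p = 7.18e-13, adjusted p = 0.301 with an estimated correlation). Of 21 body wall muscle genes, 15 fell, 0 rose and 6 did not pass, with the troponin gene tnt-2 at -0.37, which no longer passed without day 10 (-0.24). There were 16 down and 1 up when adjusted over the list alone (camera adjusted p = 8.33e-05, adjusted p = 0.346 with an estimated correlation). Of 12 small heat shock proteins, 10 fell, 0 rose and 2 did not pass. There were 10 down when adjusted over the list alone (camera adjusted p = 0.00309, adjusted p = 0.26 with an estimated correlation). Camera called 29 of the 42 lists with day, 7 higher and 22 lower, and 0 with an estimated correlation. Without day 10, 12 of the 29 calls held and the proteasome list turned to -0.02. The small heat shock call was lost (camera adjusted p = 0.0711), and the medians per day shrank from -0.17 to -0.10 for neuropeptides, from -0.09 to -0.05 for collagens, from -0.17 to -0.05 for small heat shock proteins and from -0.16 to -0.09 for muscle. Without day 4 they were -0.27 for neuropeptides and -0.27 for small heat shock proteins.

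**Figure D2:**
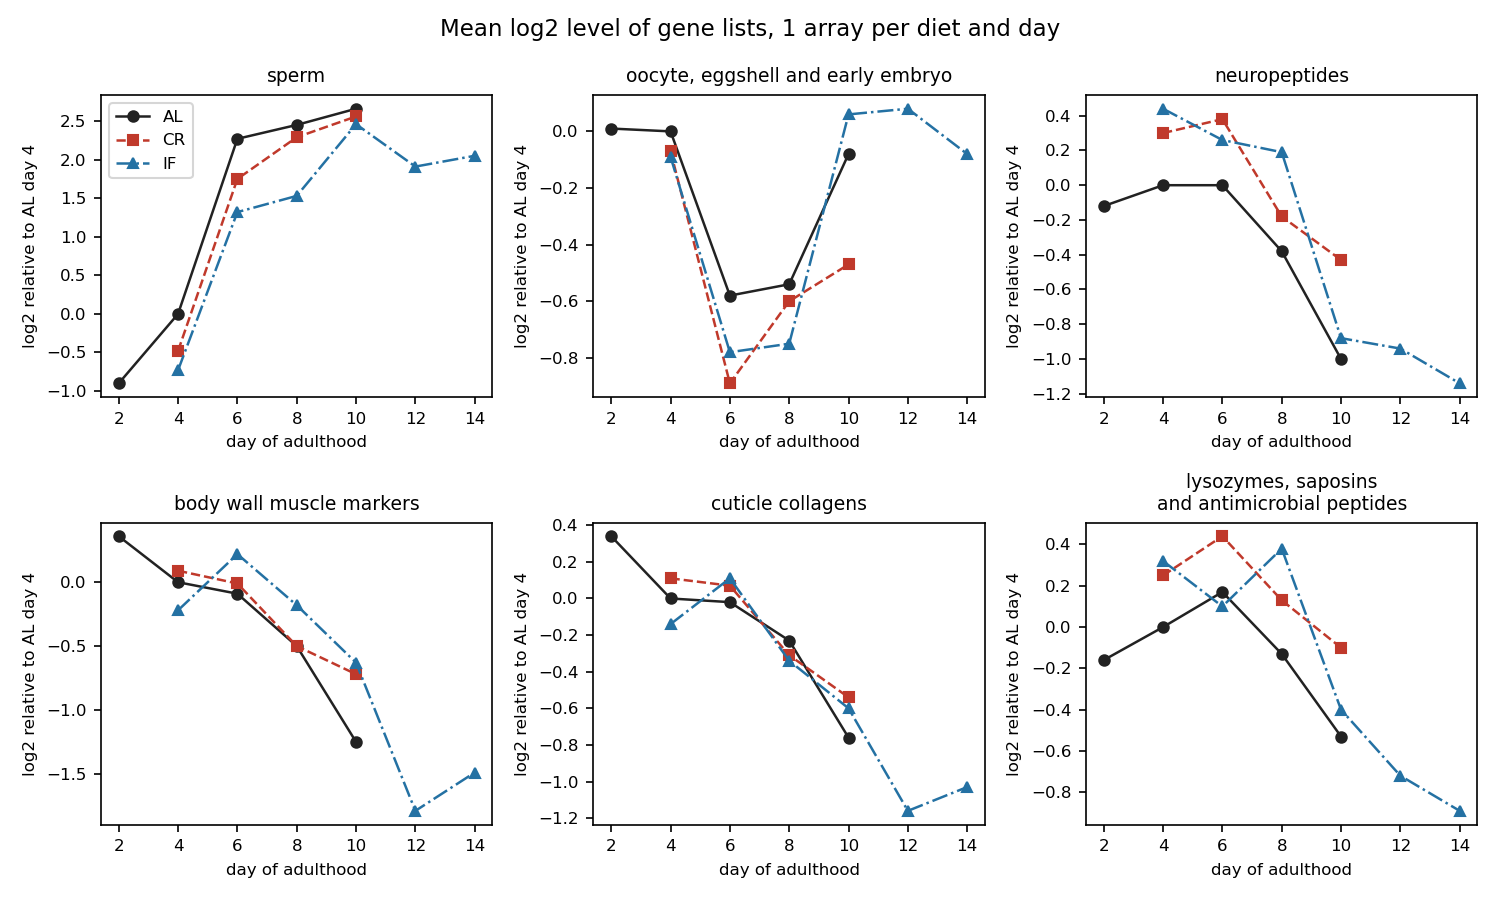
Mean log2 level of 6 gene lists relative to the AL array of day 4 (vertical axis) against day of adulthood (horizontal axis), 1 point per array, for AL (black circles), CR (red squares) and IF (blue triangles). The sperm list in AL stood 2.27 above its day 4 level on day 6, while IF stood at -0.73 on day 4 and 1.32 on day 6.

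Slopes were compared between diets to ask whether restriction changed the course with day. These fits had a line per diet and no day factor. Departures from a line that the diets shared therefore stayed in the residual spread, which makes calls harder to reach. A count of 0 thus does not show an unchanged course. For CR against AL 0 genes passed by limma, with 202 at an unadjusted p under 0.05, and the smallest p-values belonged to srh-168 (0.14 per day), F25A2.1 (0.34), clx-1 (0.44), B0252.1 (-0.23) and amt-1 (-0.28). For IF against AL 0 genes passed, with 407 at an unadjusted p under 0.05, and the smallest belonged to clec-190 (0.25), T01H10.4 (-0.19), lipl-2 (0.29), bgnt-1.4 (-0.23) and the metallothionein gene mtl-1 (0.44), all at an adjusted p of 1. The vitellogenin list differed in slope between IF and AL by a median of 0.07 per day (0 when adjusted over the list alone, camera adjusted p = 0.000253, adjusted p = 0.434 with an estimated correlation). The body wall muscle list had a higher slope in IF than in AL, by a median of 0.12 per day (0 when adjusted over the list alone, camera adjusted p = 7.18e-08, adjusted p = 0.636 with an estimated correlation). For the slope differences camera called 12 of the 42 lists in IF and 2 in CR, and 0 with an estimated correlation. A further quantile normalization kept 7 of the 12 and 1 of the 2, and array weights kept 11 and 0.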

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

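The tests of larval markers, of a falling share of somatic RNA and of the CR array of day 10 were chosen only after the results were seen. The rule for the day read from the AL course was made stricter after its readings were seen, and the rule for the germline lists of days 6 to 10 was changed more than once after their values were seen.

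Of 153 groups of arrays tested for a single array far from the others, 5 had one. Chance gives about 7.7 at 1 in 20 for arrays without a trend, whereas these arrays ran over days. On the IF array of day 14 the 3' signal of the phe control exceeded the 5' signal by 1.01 log2 units, beyond the other IF arrays. On the IF array of day 6 the difference for the cre control was 0.48. On the CR array of day 6 the mean of the list of other heat shock proteins and chaperones was 9.59, against 9.85 on each other CR array, and that of insulin-like peptides was 6.97, against at most 6.65. On the IF array of day 4 the sperm list had a mean of 7.12, against 9.18 to 10.32 on the other IF arrays. The day 4 arrays of AL and CR were low too, at 7.86 and 7.38, against 10.13 and 9.61 on day 6. This flag thus follows the change with day and does not set that array apart.

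The difference between IF and the other diets changed from days 4 and 8 to days 6 and 10 for 157 genes, by a test on the 12 matched arrays. The day effects of that fit came from AL and CR together, so the CR arrays enter these calls. Of these, 110 were higher and 47 lower on days 4 and 8, and 145 passed against AL on days 4 and 8. The 6 IF arrays alone gave 0, and their 10 splits into 3 and 3 are too few for a share under 0.05; the highest other split, days 4, 12 and 14 against days 6, 8 and 10, gave 234 genes, which points to a structure of the samples that was not tested further.

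The 1782 probe sets without a single listed gene, which the comparisons left out, held calls too. In CR 16 passed, 15 higher and 1 lower. In IF 115 passed, 33 higher and 82 lower, and with day 444 passed, 260 rising and 184 falling.

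The rise of sperm genes with day, from a list mean of 7.86 to 10.13 between AL days 4 and 6, was weighed against 3 technical explanations. Younger progeny making sperm would bring larval cuticle and molting transcripts. Of 14 such markers 0 rose and 8 fell with day, with a median change of -0.9 from day 4 to day 10. Their median level on day 4 was 7.35, and cuticle collagens fell with day as a list, so a falling adult signal could hide a contribution. The markers give no sign of progeny but cannot exclude them. A falling share of somatic RNA would raise germline classes alike, but the median change per day of the oocyte list lay below that of the sperm list (-0.547, permutation p = 1e-05, the smallest that 100000 resamples can give), a value that rests on day 4, since without it the oocyte list rose by 0.15 per day. For days 6 to 10 the 4 germline lists rose and 5 of the 6 somatic lists fell (hypodermis markers were not called, camera adjusted p = 0.0805). The rises differed by up to 0.128 per day (permutation adjusted p = 0.00052). After removal of the relation of change to level within lists, 4 of the 6 pairs of lists still differed (0.098 for the same pair, permutation adjusted p = 0.00117). For days 6 to 10 this argues against such a share as the whole cause and leaves it open as a part. From AL day 4 to day 6 the sperm list rose by 2.27. The 6 somatic lists moved by -0.09 to 0.07, and the oocyte, meiotic and germ granule lists by -0.58, -0.11 and 0. In CR and IF sperm rose and the other germline lists fell. The largest somatic fall there was that of CR hypodermis markers, from 8.45 to 8.1. With 1 array per diet and day, these values argue against a falling somatic share for that step. The permutations, also that of the oocyte list, moved genes between lists. Their p-values measure the spread between genes, not between arrays or worms. Males cannot be told apart, since their markers changed by -0.05 from a day 4 level of 5.05, in the lowest part of the range, and age itself stays open and untested.

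The CR calls were weighed against chance and against the weak 5' signal of the CR array of day 10. Of 100 reassignments of the 3 diets within days, only the real one gave 292 genes, and the highest other gave 56. This argues against chance labels over the 3 diets together. It cannot decide on CR against AL alone, since the IF labels moved too. Loss of 5' signal as the whole cause is argued against by the 231 genes that passed without that array, 191 of them among the 292. A share of 0.877 of the called genes, 256 of 292, kept at least 0.8 of their difference without it. That share alone cannot decide, since all 292 had the same sign on every matched day. Loss of 5' signal stays open as a part, and for the 5 lists of the 18 that lost their call without that array. Differences between cultures, with 1 per diet and day, were not tested, and diet stays open as the biological explanation.

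Diet differences ran against the change with day. Across genes, which are not independent replicates, the IF difference correlated with the change per day at -0.707 and the CR difference at -0.469. Simulated values for IF ran from -0.032 to 0.033, but their noise was drawn for each gene apart and leaves out shared variation. Of 100 reassignments of the diets, 2 were as low for IF, the real one included. The others ran from -0.719 to 0.745, so correlations of this size also arise with reassigned diets, in either direction. A younger profile may lie behind the negative correlations, since all 8 CR and IF arrays were read as earlier than their day from the AL course. The error of that reading keeps it open, and a younger profile and a misreading cannot be told apart: the 4 matched AL arrays, left out in turn, were read from -1.63 to 0.89 days off, 2 of them as earlier, and CR arrays were read on average -0.36 days (SD 1.1) and IF arrays -1.09 days (SD 1.58) from the AL array of the same day, with an exact two-sided p of 0.375 for IF and a larger one for CR, where 4 pairs allow 0.125 at the lowest.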

How the results depend on the processing

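The removal of the CR array of day 10 from comparisons without CR, and of whole days from the change with day, were chosen only after the results were seen. No named gene reversed: 7028 values under alternatives kept their side of the threshold, 44 newly passed and 1215 no longer passed, of which 637 came from leaving out 1 array and 270 from the fit with no day term. Array weights gave 679 genes for CR against AL, 17 for IF against CR, 13 for IF days 6 and 10 against AL and 45 for the periods inside IF. With no replicate block, that is no day term, the counts were 3 for CR, 1 for IF, 34 for IF days 4 and 8 and 0 for IF days 6 and 10. Only the arrays compared gave 460 for CR, 29 for IF against CR, 303 for IF days 4 and 8 and 50 for IF days 6 and 10. IF as 1 group gave 38 for CR and 687 for IF. The periods on 12 matched arrays gave 157. The change with day gave 3948 with dim genes left out, where 8559 genes were tested, and 2691 without day 10. Leaving out 1 array gave 96 to 321 genes for CR, 336 to 1693 for IF, 0 to 9 for IF against CR, 302 to 1426 for IF days 4 and 8, 0 to 91 for IF days 6 and 10, 0 to 67 for the periods and 4139 to 6474 for the change with day. The slope differences gave 0 under each alternative run. For the counts that moved, the cause was not tested beyond the fewer genes or arrays. The other alternatives kept each count within 1.5 times, and camera with an estimated correlation called 0 lists in each comparison. By fry 1 list was called for CR, 13 for IF, 15 for IF days 4 and 8, 32 for the change with day and 0 elsewhere. No list call turned under a further quantile normalization or the mean of probe sets; array weights turned 2 inside IF, and removal of the CR array of day 10 turned 1 for IF against CR. Signal near background limits dim genes such as the male markers.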

Other observations

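No test in this part was chosen only after the result was seen. The AL array of day 2, from worms still on live bacteria and with no counterpart in the other diets, is given as values. Its vitellogenin list had a mean log2 level of 13.72, against 13.01 on AL day 4, and its small heat shock list 8.04, against 8.93. The mean of the DAF-16 class I genes was 9.16 on day 2 and 10.16 on day 4. On the IF arrays of days 12 and 14 the vitellogenin means were 11.77 and 11.62 and the body wall muscle means 8.83 and 9.13, without arrays of those days in the other diets.

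The 3 diet labels were reassigned within days in 100 ways, the real one included. For IF against AL only the real assignment, 1 of 100, gave 1151 genes, and the highest other gave 80. This argues against chance labels over the 3 diets together. It cannot decide on IF against AL alone, since the CR labels moved too. For IF against CR the real count was 0, which all 100 of 100 reach by construction, so the test says nothing about chance. The highest other, 1249, gave every AL array the CR label, which points to the structure of AL against the restricted diets. For the slope differences of CR and of IF against AL the real count was 0, which all 100 of 100 reach by construction, and the highest other was 0. For the 6 IF arrays the 10 splits are too few for a share under 0.05; the real count was 0, which 10 of 10 reach by construction, and the highest other was 234.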
